A study of Homo sapiens and Oncorhynchus mykiss with 552 samples.

How the data were processed

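RNA was measured in 552 libraries from 2 cell lines, Caco-2, a human colon carcinoma line, and RTgill-W1, an epithelial line from the gill of rainbow trout. Each line was exposed to extracts of soil from 11 sites at the Agbogbloshie electronic waste area in Ghana, at 8 concentrations per site with 3 replicates, next to 12 wells with the solvent DMSO alone. Per the labels' protocols, exposure began 24 hours after 35000 cells were placed in each well, and libraries were made straight from the cell lysate with a kit that reads the 3' ends of transcripts (UPXome, Qiagen). The unit of the labelled concentrations was not stated, so trends are given per doubling of the labelled number. In the table of Caco-2 site 48 the line of concentrations is shifted against the columns; the concentrations in the sample labels were used.

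The deposited tables hold whole-number counts per gene, not normalized, in 24 tables. Per the submitters' processing notes, STAR and limma were used with the human build GRCh38; no versions or roles were given, and the same build was named for the trout libraries, whose gene identifiers are trout ones. How reads were counted, and whether the counting used the strand, was not given in the sources used here. Counts of genes that overlap, lie antisense to each other or have near-identical copies were therefore treated as uncertain.

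Every sample was matched to a column by its label. The tables of the sites also held 264 repeated control columns, which were not used; 262 of them were identical to the controls' own table and 2 differed from it. Human identifiers were matched to symbols for 37615 of 37728 rows, with 113 unmatched. None of the 44260 trout identifiers could be matched to a symbol with the tables used here, so gene lists were not analysed in RTgill-W1, and only the 2 genes called in the most sites in each direction and the largest rise and fall against DMSO at sites 3 and 8 are given there, by identifier. Coordinates are those of GENCODE 29 on GRCh38.

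Caco-2 libraries held a median of 1637074 counts, from 40835 to 22903077, over a median of 14567 detected genes. RTgill-W1 libraries held a median of 236798 counts, from 9666 to 1147567, over a median of 6034 detected genes. In each line 1 gene row took most counts, ENSG00000278996 with a median of 81.7% in Caco-2 and ENSOMYG00000006898 with 87.1% in RTgill-W1. The median total over the other rows was 281162 in Caco-2 and 33788 in RTgill-W1, which is the depth that bears on all other genes. Libraries with fewer than 163707 counts in Caco-2 or 23680 in RTgill-W1, 10 times less than their line's median total, were left out of the concentration trends, 11 in Caco-2 and 2 in RTgill-W1.

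In each line, edgeR 4.0.16 fitted an intercept and a slope on log2 of the labelled concentration for each site to all treated libraries, 253 with 13029 genes in Caco-2 and 262 with 1716 genes in RTgill-W1. Counts were scaled with TMM, genes were kept by filterByExpr, and the quasi-likelihood test with Benjamini-Hochberg adjustment was used with a threshold of 0.05 on adjusted p. From these fits came the genes called at each site, the mean of the 11 slopes, the difference between the 8 Caco-2 sites that share a concentration series, and the difference between RTgill-W1 sites 49 and 74. Sites whose libraries shared pools with the controls were also set against DMSO at their highest concentration, sites 2 and 16 in Caco-2 and 3 and 8 in RTgill-W1, in a fit of 9 groups with no library left out. Slopes are in log2 units per doubling of concentration with their standard error (SE), and CPM, the counts scaled to a common library total, use the scaled library totals.

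Members of 21 gene lists, fixed before the data were examined, were tested with camera (limma 3.58.1) on the slopes, with a preset correlation of 0.01 between genes and adjustment over all lists and sites. The lists were the aryl hydrocarbon receptor battery, oxidative stress (NRF2), metallothioneins and zinc export, heat shock, the unfolded protein response, the integrated stress response (ATF4), p53 and DNA damage, cholesterol synthesis, fatty acid oxidation (PPAR), proliferation, inflammation (NF-kB), interferon response, immediate early genes, hypoxia and glycolysis, xenobiotic metabolism (PXR), ribosomal proteins, mitochondrially encoded genes, enterocyte differentiation, other intestinal lineages, epithelial markers, and mesenchymal, immune and blood markers. The rule for named genes, also fixed before, took the 12 rising and 12 falling genes called in the most sites, the largest rise and fall per site among genes of at least 10 CPM, the 4 largest rises and falls against DMSO, and the members of the first 4 lists and of the cholesterol list. Members of other lists are given as examples of their list. Only members that passed the filter on low counts were tested, such as 5 of 15 in the NF-kB list, and member counts refer to these. Some members of these lists are not reported here.

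Alternatives were the replicate number as a block, DESeq2 1.42.0, limma-trend with a prior count of 2, upper-quartile scaling, no filter on low counts, all libraries kept, no highest concentration, each replicate left out in turn, an estimated correlation in camera, and an exchange of 2 RTgill-W1 libraries whose labels give both orders. Summing the 3 libraries of a concentration, leaving out the row with most counts, and leaving out the 5 libraries with a count of 0 in that row were added after the data were seen. Nothing in the labels says that the 3 replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

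Same-numbered replicates of a site share a library pool, and the labels tie controls to the same runs. The deviations of Caco-2 libraries from the mean of their site and concentration correlated at a median r of 0.17 over 847 pairs with the same replicate number and at -0.0924 over 1694 pairs with different numbers. In RTgill-W1 the medians were 0.153 and -0.0746. The deviations within a site and concentration sum to 0, so positive medians for the same number bring negative ones for different numbers. The negative medians are therefore not a separate observation. The numbers were taken to pair the libraries on the ground of the shared pools. The main fits did not use this pairing, which entered only in the alternative with a block. Against DMSO, Caco-2 sites 2 and 16 had 666 and 98 calls in the main fit and 782 and 180 with the run as a block. RTgill-W1 sites 3 and 8 had 93 and 52 in the main fit and 116 and 78 with the block.

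The fits were tested on simulated data with 200 changed genes. At Caco-2 site 3 they called 17% of genes with a slope of 0.2 and 80% with a slope of 0.4, and 2.02% of the calls were unchanged genes. With a random deviation per gene and well of SD 0.4 shared by the 3 libraries, 24.4% of the calls were unchanged genes. When the 3 libraries were summed this share was 0%, and 58% of the genes with a slope of 0.4 were still called. The SD was set and not estimated from the data. With it limma-trend called 4 genes at the unchanged site 5. In the real site 5 wells with concentrations dealt out anew it called a median of 212. The simulated shares therefore do not give the error of the real calls. At RTgill-W1 site 3 the fit called 82% of genes with a slope of 0.4, and the shares of unchanged genes among calls were 1.94%, 11.7% with well deviations and 4.94% with these and summed libraries. Against DMSO at Caco-2 site 2, 100% of genes raised by 4 and 66% of genes lowered by 4 on the log2 scale were called; at RTgill-W1 site 3 these shares were 100% and 96%. A simulated list of 20 rising genes reached a camera p of 1.51e-34 at Caco-2 site 3, and 2 of 20 unchanged lists had p under 0.05. Lists were simulated only without well deviations. The analyses ran in R 4.3.3 and Python 3.11.15.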

Results

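Soil extracts from 11 sites of an electronic waste area were put on a human colon line, Caco-2, and on a rainbow trout gill line, RTgill-W1, to follow their molecular effects over a range of concentrations. Each line gave 264 treated libraries, 3 at each of 8 concentrations per site, and 12 libraries from wells with DMSO alone, in 3 runs of 4 wells. Total counts per library ranged from 40835 to 22903077 in Caco-2 and from 9666 to 1147567 in RTgill-W1. In Caco-2, 8 sites shared 1 labelled series from 0.075 to 9.38, while the highest label was 3.1 at site 8, 5.82 at site 48 and 2.85 at site 49. In RTgill-W1 only sites 49 and 74 shared a series, again from 0.075 to 9.38, and the highest label of the others lay between 0.27 at site 8 and 8.88 at site 20.

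The first comparison asked which Caco-2 genes moved with concentration, averaged over the 11 extracts. CYP1A1 (ENSG00000140465), the cytochrome P450 enzyme induced through the aryl hydrocarbon receptor, rose by 0.86 ± 0.027 log2 units per doubling (SE; edgeR adjusted p = 1.12e-84) and was called at all 11 sites. Its level at the highest concentration ranged from 19.4 ± 9.35 CPM at site 49 to 179.8 ± 47.8 CPM at site 2 (SD, n = 3), against 0.55 ± 0.776 CPM in the DMSO wells (SD, n = 12, scaled together with site 2). TIPARP, another target of that receptor, rose by 0.31 ± 0.0198 per doubling and was called at 7 sites. MT2A, a metallothionein that binds zinc, copper and cadmium, rose by 0.87 ± 0.0541 (adjusted p = 1e-36) and was called at 8 sites. SOS1, an exchange factor that activates RAS, rose by 0.24 ± 0.0129 and was called at 11 sites. In all, 1355 genes rose and 1369 fell with concentration.

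Other genes called as rising in the most sites were the glucose transporter SLC2A1 (0.18 ± 0.0154 per doubling, 6 sites), the amino acid transporter SLC7A5 (0.16 ± 0.0155, 6 sites) and SEL1L3 (0.18 ± 0.0246), which rose at 6 sites and fell at 1. MT1G was called at 6 sites, but its mean slope could not be estimated (adjusted p = 1) because it had no counts at some sites. LINC00511 (9 sites), DYNLRB2-AS1 (8 sites), LINC00886 (7 sites) and EDC3 (7 sites) rose by 0.17, 0.20, 0.23 and 0.15. The non-coding ones overlap or lie near other genes, so their reads are uncertain as to source. EDC3 lies 23250 bases past the 3' end of CYP1A1 on the same strand, and LINC00886 lies 40576 bases past TIPARP on the opposite strand. CYP1A1 spans bases 74719542 to 74725610 of chromosome 15, EDC3 74630558 to 74696292 of the same chromosome, and MT2A 56608199 to 56609497 of chromosome 16; values are per gene.

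Falling genes included FGB and FGG, which code for the beta and gamma chains of fibrinogen, a plasma protein made by the liver. FGB fell by 0.26 ± 0.0207 per doubling (adjusted p = 3.77e-25; 7 sites, with a rise at site 74 that was lost with libraries summed) and FGG fell by 0.28 ± 0.0266 (6 sites). FGB at site 2 was 1.1 ± 1.17 CPM at the highest concentration (SD, n = 3), and at site 7 it went from 25.3 ± 9.25 CPM at the lowest to 3.3 ± 2.92 CPM at the highest. DNAJC15, a mitochondrial co-chaperone, fell by 0.26 ± 0.0147 at the mean of the sites and was called at 8 of them. The transcription factors SOX5 and SOX6, the semaphorin receptor PLXNC1 and NKD1, an antagonist of Wnt signalling, fell by 0.18, 0.15, 0.24 and 0.24. SLC14A2, a urea transporter, fell by 0.34 ± 0.0231, and FYB2, GRIK4, EPSTI1 and CPA6 fell by 0.33, 0.21, 0.21 and 0.19.

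These calls came from edgeR's quasi-likelihood test on 13029 genes. With the 3 libraries of a concentration summed into 1, the mean trend kept 1564 of its 2724 calls and gave 1665 in all. Of the rising genes CYP1A1, TIPARP, MT2A, SOS1 and MT1G were then called at 11, 7, 6, 8 and 6 sites, SLC2A1, SLC7A5 and SEL1L3 at 2, 3 and 1, and LINC00511, DYNLRB2-AS1, LINC00886 and EDC3 at 1, 3, 2 and 2. FGB, FGG and DNAJC15 fell at 4, 4 and 5 sites and EPSTI1 and CPA6 at 1 and 2. The calls at single sites counted wells as replicates although the 3 libraries of a concentration mostly came from the same well position of different plates, which the plot of correlations between wells describes. At every site the concentration also went with the row of the plate, the highest in row A, so a trend over rows cannot be taken out of these slopes.

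**Figure D1:**
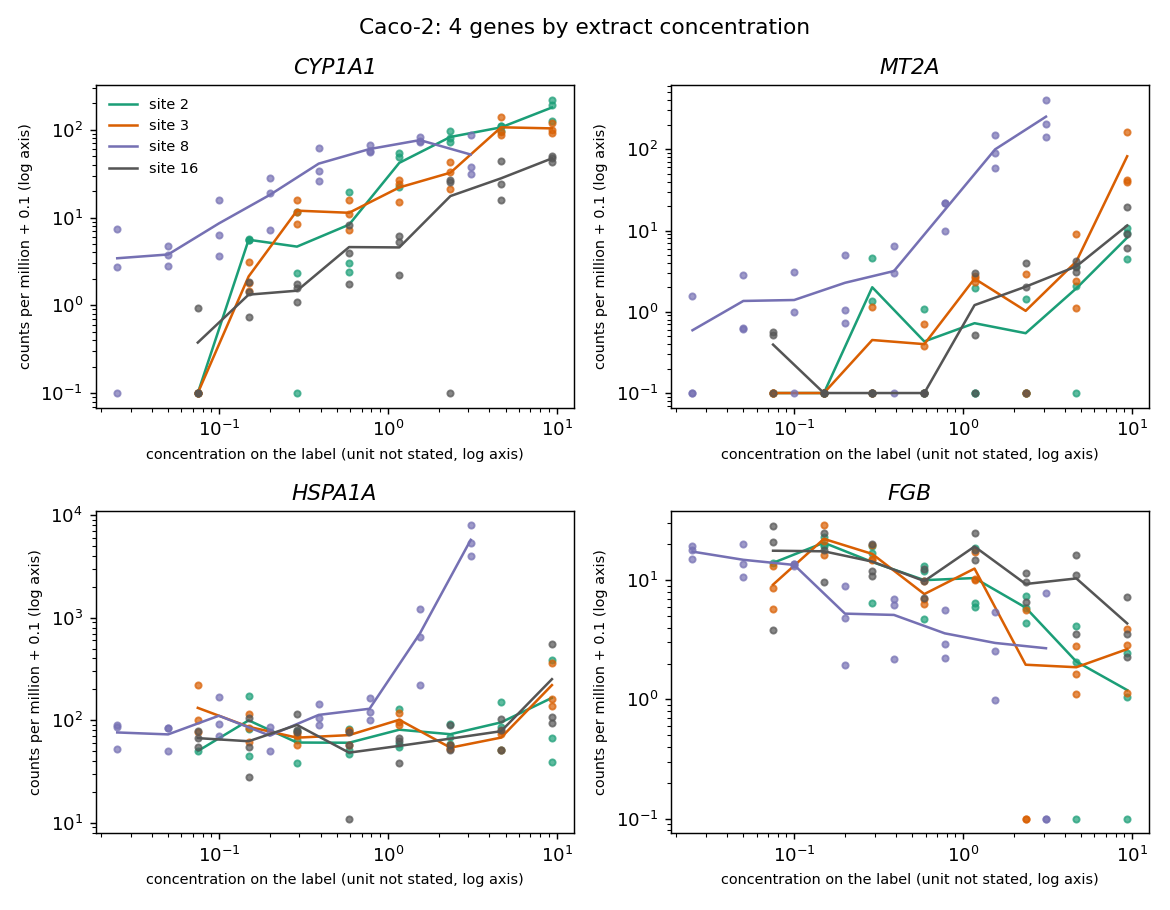
CPM of CYP1A1, MT2A, HSPA1A and FGB in Caco-2 against the labelled concentration (unit not stated) at sites 2, 3, 8 and 16, both axes logarithmic with 0.1 added to CPM; points are libraries and lines join the means of up to 3 libraries. CYP1A1 rose at all 4 sites, and HSPA1A at site 8 went from 75.7 CPM at the lowest concentration to 5749 CPM at the highest.

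Of the gene lists fixed in advance, the aryl hydrocarbon receptor battery rose at all 11 sites (camera adjusted p from 1.9e-14 at site 30 to 0.00929 at site 74). Of its 14 listed members 5 passed the filter on low counts. All 5 rose in the mean trend, and all 5 when adjusted over the list alone. The filter used all treated libraries, so a gene near 0 at low concentrations can pass through the wells where it rose. The members left out were not tested. At single sites 1 to 4 members rose, and at sites 16, 20, 49 and 74 CYP1A1 alone. The 5 were CYP1A1, TIPARP, the receptor's repressor AHRR (0.20 ± 0.0443), the quinone reductase NQO1 (0.11 ± 0.0159) and UGT1A6 (0.27 ± 0.0566), which shares exons with other UGT1A genes and is uncertain. The list was called at all 11 sites with an estimated correlation too, and with libraries summed.

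Metallothioneins and zinc export rose at sites 2, 3, 5, 7, 8, 16 and 30, with adjusted p from 1.36e-19 at site 8 to 0.0391 at site 2. At site 2, where 2 members rose, the call was lost with an estimated correlation (adjusted p = 0.167) and with libraries summed (0.138). MT2A rose from 0.493 ± 0.854 CPM at the lowest to 252 ± 140 CPM at the highest concentration at site 8, and from 0.21 ± 0.364 to 94.3 ± 57.5 CPM at site 7 (SD, n = 3). MT1X at site 8 stood at 208 ± 53 CPM at the highest concentration, and MT1G at 62.6 ± 18.4 CPM, while neither had a count in the 3 libraries at the lowest. SLC30A1, a zinc exporter, rose at site 8 by 0.63 ± 0.125 per doubling. Of the 15 listed members 5 passed the filter. In the mean trend 3 of these 5 rose, also 3 over the list alone, while MT1G and MT1H could not be tested there. Metallothionein genes resemble each other closely, so the split of reads among them is uncertain.

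The oxidative stress (NRF2) list was called up at sites 2, 3, 5, 7, 8, 16, 30 and 48 (adjusted p from 4.06e-15 at site 3 to 0.0226 at site 16). The calls at sites 5, 16 and 48 were lost with an estimated correlation, with adjusted p of 0.135, 0.345 and 0.334, and the call at site 16 also with libraries summed (0.232). Of the 20 members 12 rose at site 3 and 10 at site 8, while at site 16 1 rose and 1 fell and at site 48 no member passed, also over the list alone. In the mean trend 15 members rose and none fell, and 16 passed over the list alone. SLC7A11, the cystine importer, rose by 0.72 ± 0.0788 per doubling at site 2, by 0.64 ± 0.0771 at site 3, by 0.61 ± 0.0772 at site 7 and by 0.59 ± 0.0789 at site 8. HMOX1, which breaks down haem, went from 6.68 ± 3.19 to 183 ± 58.6 CPM at site 8 (SD, n = 3). GCLC and GCLM, the catalytic and modifier subunits of the first enzyme of glutathione synthesis, rose by 0.35 ± 0.0447 and 0.42 ± 0.0854 at site 3.

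The integrated stress response list, the targets of the transcription factor ATF4, was called up at sites 2, 3, 5, 7, 8, 16 and 30 (adjusted p from 5e-14 at site 8 to 0.0378 at site 16). At site 16 the adjusted p was 0.133 with an estimated correlation and 0.0854 with libraries summed, with 1 member rising, and at site 30 no member passed over all genes and 1 over the list alone. In the mean trend 9 of 11 members rose, 9 also over the list alone, among them ASNS, the asparagine synthetase (0.28 ± 0.0426), TRIB3 (0.19 ± 0.0277) and PSAT1 of serine synthesis (0.19 ± 0.0194). At site 8 ATF3 rose by 0.73 ± 0.0845 and DDIT3, also known as CHOP, by 0.72 ± 0.103 per doubling. DDIT4, an inhibitor of mTORC1, rose by 0.97 ± 0.13 at site 3.

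Heat shock genes were called as a list at site 8 (adjusted p = 6.4e-19), where 9 of 13 members rose, 12 over the list alone. HSPA1A rose there from 75.7 ± 21.0 to 5749 ± 2026 CPM and HSPA1B from 30.3 ± 19.3 to 2114 ± 846 CPM (SD, n = 3). Both code for the inducible HSP70 and are nearly identical, so each is uncertain on its own. DNAJB1, a partner of HSP70, went from 9.02 ± 2.44 to 283 ± 132 CPM, and BAG3, its exchange factor, from 14.9 ± 5.78 to 332 ± 133 CPM. The list did not pass at the other 10 sites. At site 16 its camera adjusted p was 0.0572, and 0.048 with the replicate number as a block. There it was 0.516 with an estimated correlation and 0.183 with libraries summed. Since the concentrations of site 8 differ from those of the other 10 sites, the difference was not tested. HSPA1A and HSPA1B fell at site 5 by 0.25 and 0.23 per doubling, calls that were lost with libraries summed (adjusted p = 0.349 and 0.38). In the mean trend 8 members of the list rose, 9 over the list alone, and 5 with libraries summed. Of these 8, HSPA1A, HSPA1B, DNAJB1, BAG3, HSPH1, HSP90AA1 and HSPD1 were each called as rising at 1 site and HSPA4L at 0. The mean trend therefore does not show a rise shared by the extracts.

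The unfolded protein response list was called up at sites 3 and 8 (adjusted p = 7.46e-06 and 0.00741), where 7 and 3 of 14 members rose, and down at site 16 (0.0378; 0.112 with libraries summed), where no member passed, also over the list alone. With an estimated correlation the adjusted p was 0.0185, 0.203 and 0.347. HSPA5, the main chaperone of the endoplasmic reticulum, rose from 60.3 ± 6.89 to 468 ± 186 CPM at site 3 and from 107 ± 36.6 to 797 ± 215 CPM at site 8 (SD, n = 3). Proliferation genes fell at site 8 (adjusted p = 1.28e-05), where 5 of 16 members fell, 7 over the list alone and 1 with libraries summed; MKI67, a marker of cycling cells, went from 186 ± 44.3 to 43.9 ± 26.9 CPM. That list was called up at site 74 (adjusted p = 0.0393; 0.371 with an estimated correlation and 0.181 with libraries summed) with no member past the threshold over all genes. The fatty acid oxidation list was called up at site 2 (adjusted p = 0.0018), where 2 of 9 members rose, 3 over the list alone, and CPT1A, the gate of fatty acids into mitochondria, rose by 0.37 ± 0.0704 per doubling. At site 3 that list did not pass (camera adjusted p = 0.0577). There it had 0.0373 with the replicate number as a block, 0.0255 with libraries summed and 0.304 with an estimated correlation.

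Over all 21 lists and 11 sites, 54 of 231 pairs were called, 47 up and 7 down. Of these, 34 held with an estimated correlation and 47 with the libraries summed, in the same direction. Dealing the concentrations out anew to the wells gave a median of 20 pairs in limma-trend, against 56 with the real order. Single pairs may therefore be due to chance.

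**Figure D2:**
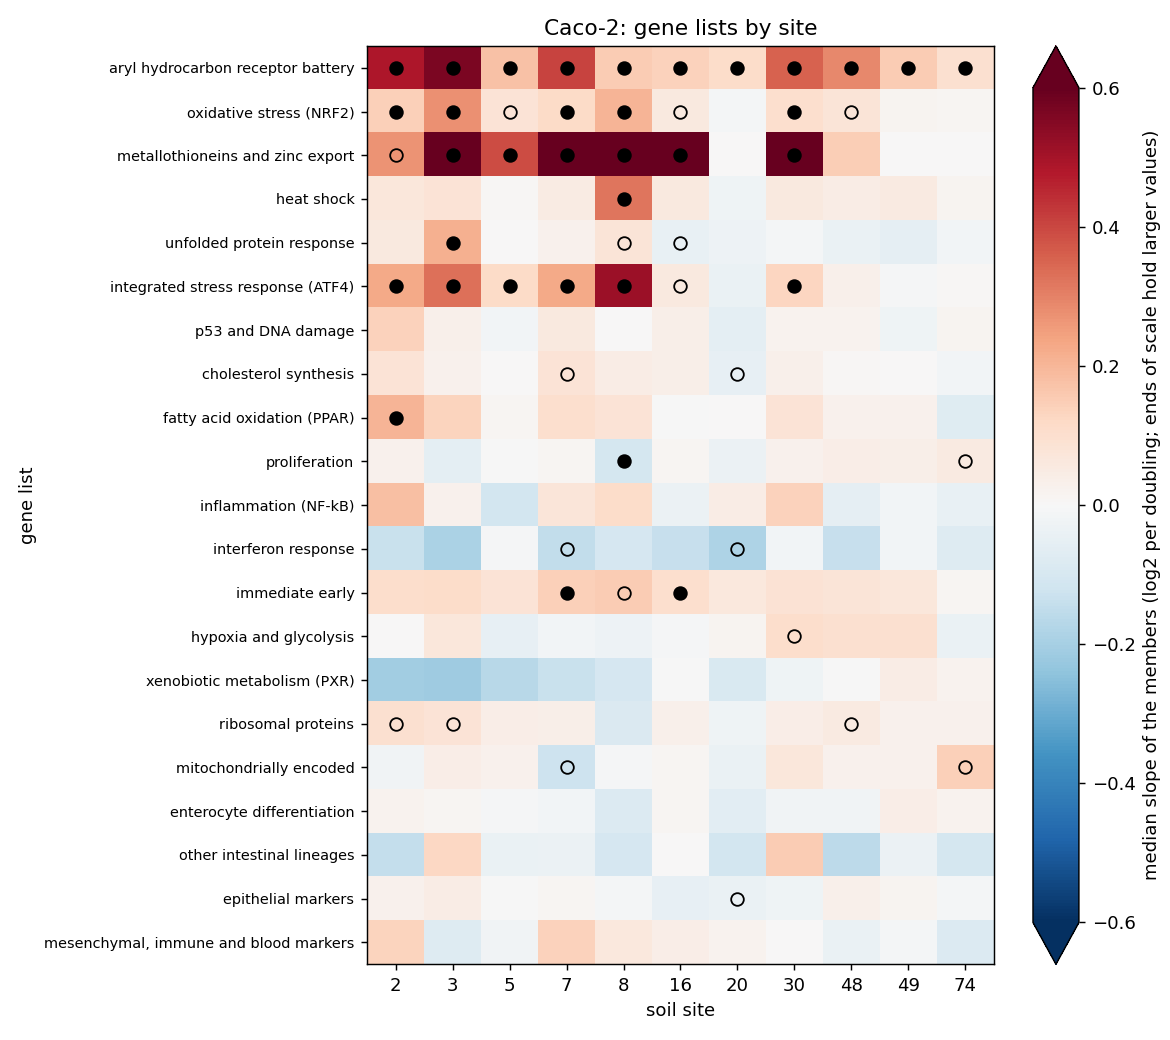
Median slope (log2 per doubling of labelled concentration) of the members of each gene list at each of the 11 sites in Caco-2. Filled circles mark camera calls that hold with an estimated correlation, 34 of them, and open circles the calls that do not, so that the 54 calls sit mostly in the aryl hydrocarbon receptor, NRF2, metallothionein and ATF4 lists.

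The next comparison took each Caco-2 extract by itself. At site 8 the most genes were called, 528 rising and 784 falling, followed by site 3 with 670 rising and 556 falling. Chance was not excluded for the counts at sites 3, 5, 7, 16, 20, 48, 49 and 74. This was judged on limma-trend counts, and the edgeR counts given here were not set against concentrations dealt out anew. Concentration also went with the plate row at every site and the highest labels differed, so these counts do not rank the extracts. Sites 5, 2, 7 and 49 had 198, 353, 252 and 213 rising and 581, 310, 232 and 221 falling genes. Sites 48, 74, 16, 20 and 30 had 125, 63, 175, 58 and 54 rising and 190, 197, 79, 129 and 67 falling genes. With limma-trend these 5 sites had 117, 44, 9, 66 and 28 calls in all. With no filter on low counts sites 20 and 30 had 476 and 244. Without 1 replicate every site had fewer calls, and at its lowest by over 1.5 times, such as 546 to 817 at site 3 and 770 to 966 at site 8. At site 5 the share that rose was 25.4%, and 35.9% with DESeq2, which changes the scaling and the test together. At site 49 the share was 49.1%, and 34% with DESeq2.

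Among genes with a mean of at least 10 CPM at the site, the steepest rising slopes were in MT2A at sites 3 (1.69 ± 0.136 per doubling) and 7 (1.70 ± 0.141), MT1G at site 8 (2.13 ± 0.14) and CYP1A1 at sites 20 (1.05 ± 0.0923) and 30 (0.90 ± 0.0835). RPL34, a ribosomal protein, rose at site 48 from 8.95 ± 3.03 to 1647 ± 337 CPM. RPL34 also varied widely in the 12 DMSO wells, at 76.1 ± 159 CPM (SD, scaled together with site 16). Its 3 site 48 libraries at the highest concentration shared a well position, so a deviation of that well was not parted from the extract. MED31, a Mediator subunit, rose at site 49 from 0.737 ± 1.28 to 87.7 ± 64.1 CPM, with 2.67 CPM averaged over the sites. The same limit holds for MED31, whose 3 libraries at the highest concentration of site 49 also shared a well position. CKS2, which binds cyclin-dependent kinases, rose at site 2 to 449 ± 756 CPM, a spread wider than its mean, and at site 16 from 28.4 ± 16.5 to 177 ± 212 CPM. RAC1, a small GTPase, had a slope of 0.85 ± 0.125 at site 5 with 39.6 ± 18.6 CPM at the lowest and 45.6 ± 17.8 CPM at the highest concentration. NDUFA7 rose at site 74 by 0.96 ± 0.152; it overlaps RPS28, so both are uncertain.

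With the same limit, the steepest falling slopes were in AK4P3 at site 2, a pseudogene whose reads are uncertain, MAGOH at site 3, LAMTOR1 at site 5, RASL11A at site 7 and RPS28 at site 8. The others were CLK1 at site 16, GSDMD at site 20, RBX1 at site 30, MRPS2 at site 48, NHSL2 at site 49 and H3-5 at site 74. NHSL2 went from 588 ± 115 to 3.98 ± 1.35 CPM and H3-5 from 102 ± 56.1 to 1.4 ± 0.248 CPM, and RASL11A from 18.6 ± 13 to 0.772 ± 0.731 CPM. Averaged over the sites, NHSL2 had 18.99 CPM, H3-5 8.33 and RASL11A 12.13. For each of these genes the 3 libraries at the lowest concentration shared a well position. A deviation of that well was therefore not parted from the extract. Other falls do not show between the ends: from the lowest to the highest concentration CLK1 stood at 6.17 ± 2.89 and 5.69 ± 2.39 CPM, LAMTOR1 at 11.1 ± 2.44 and 9.89 ± 2.42, RBX1 at 7.72 ± 3.89 and 6.43 ± 0.829, and MAGOH and MRPS2 were higher at the highest, at 6.05 ± 4.22 and 7.45 ± 6 and at 4.35 ± 7.53 and 4.83 ± 2.3 CPM (SD, n = 3). AK4P3 had a slope of 0.00 without replicate 1. RPS28 had a slope of 0.02 without replicate 1, and of 0.07 without the libraries with a count of 0 in the gene row that holds most counts.

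Of these 22 steepest rises and falls, 16 passed with the libraries summed; CKS2 at site 16 (adjusted p = 1), MAGOH (0.0595), GSDMD (0.359), MRPS2 (0.176), NDUFA7 (0.0704) and H3-5 (0.154) did not. Summing gave 264, 431, 172, 141 and 626 calls at sites 2, 3, 5, 7 and 8, of which 250, 414, 169, 136 and 591 were shared with the calls above. Sites 16, 20, 30, 48, 49 and 74 had 35, 9, 16, 50, 91 and 32, all of them shared except at site 49, where 85 were.

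**Figure D3:**
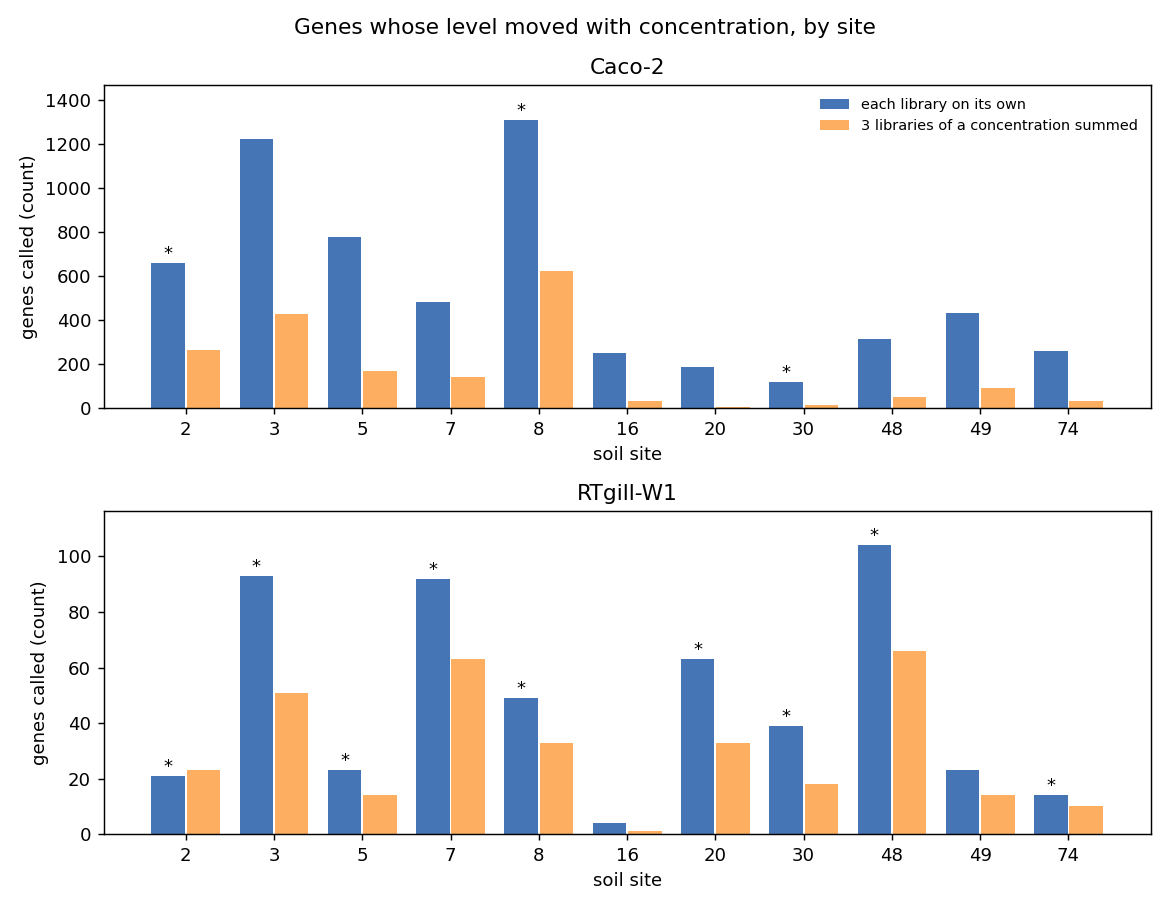
Number of genes called (edgeR, adjusted p under 0.05) at each soil site in Caco-2 and RTgill-W1, with each library on its own and with the 3 libraries of a concentration summed; bars start at 0. An asterisk marks sites where fewer than 5 of 100 ways of dealing the concentrations to wells gave as many calls in limma-trend, such as 456 calls at Caco-2 site 2 and 143 at RTgill-W1 site 48. The edgeR counts shown as bars were not judged in this way.

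**Figure D4:**
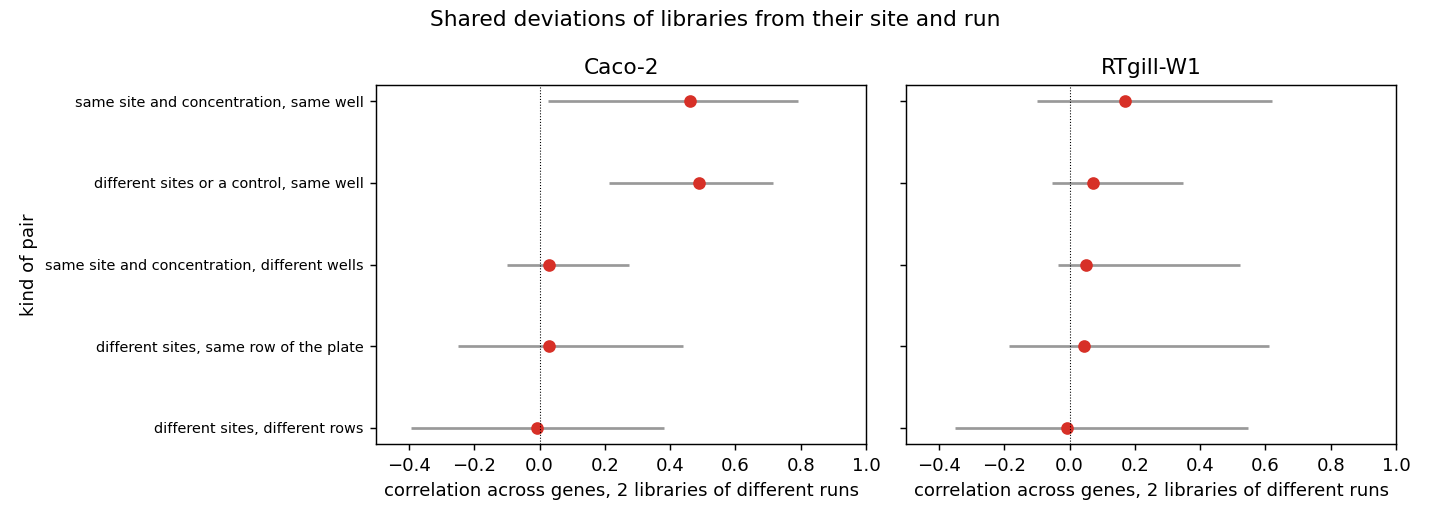
Correlation across genes of the deviations of 2 libraries from the mean of their site and run, for pairs from different runs. The trend with concentration was not taken out of these deviations. Points are medians over pairs and bars run from the lowest to the highest. In Caco-2 the median was 0.46 for the same site, concentration and well, 0.489 for different sites or a control in the same well, and 0.0287 for the same site and concentration in different wells.

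Extracts 2, 3, 5, 7, 16, 20, 30 and 74 were compared at matched concentrations in Caco-2. The slope of SLC7A11 differed among them (adjusted p = 2.27e-10), from 0.72 ± 0.0788 at site 2 to sites where it was not called. FGB also differed (adjusted p = 2.59e-11), falling by 0.53 ± 0.0822 per doubling at site 2 and rising by 0.20 ± 0.0565 at site 74, a rise that was lost with libraries summed (adjusted p = 0.743). AKR1C1, an aldo-keto reductase of the NRF2 list, differed (3.45e-12) and rose by 0.70 ± 0.0725 at site 3, with near-identical family members that leave its reads uncertain. MT2A and HMOX1 differed with adjusted p of 4.2e-05 and 0.00684, and CYP1A1 was not among the genes that differed. In all 1526 genes differed (edgeR F test over the 8 slopes), a count for which chance was not excluded: in limma-trend 429 genes differed, and 57 of 100 ways of dealing the concentrations to wells, the real one included, gave as many. With the libraries summed 92 did, of which 91 were shared; TIPARP, FGB, PLXNC1, FGG, GRIK4, PRDX1, SLC7A11 and AKR1C1 were among those of the named genes, while MT2A had an adjusted p of 0.114.

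Set against DMSO, site 2 at its highest concentration raised CYP1A1 by 8.60 ± 0.5 log2 units, from 0.55 ± 0.776 to 205 ± 55.7 CPM (SD, n = 12 and 3; edgeR adjusted p = 1.22e-14). S100P, a calcium-binding protein, rose by 5.35 ± 0.396, DDIT4 by 4.72 ± 0.625 and SLC7A11 by 4.72 ± 0.371. FGB fell by 4.04 ± 0.661, AMACR, a racemase of branched fatty acids, fell by 4.03 ± 0.805, the glypican GPC5 fell by 4.00 ± 0.442 and the laminin chain LAMA1 fell by 3.92 ± 0.695. A total of 330 genes rose and 336 fell, and 592, 225 and 220 were called without replicates 1, 2 and 3. At the lowest concentration 836 genes differed from DMSO, with 1 of the 3 libraries above the depth limit used for the trends.

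At the highest concentration of site 16, CYP1A1 rose by 6.68 ± 0.512, from 0.528 ± 0.755 to 49.9 ± 3.99 CPM (SD, n = 12 and 3; edgeR adjusted p = 8.77e-11). RPL34, the respiratory chain subunit COX4I1 and HFM1 rose by 3.04 ± 0.697, 2.91 ± 0.664 and 2.85 ± 0.617, each with a wide spread such as 633 ± 517 CPM for RPL34. FGB fell by 2.48 ± 0.467, GPC5 fell by 1.75 ± 0.285, LINC00571 fell by 1.68 ± 0.383 and the glutamate receptor subunit GRIK4 fell by 1.41 ± 0.275. Here 65 genes rose and 33 fell, and 40 differed at the lowest concentration. The count was 180 with the run as a block, 215 with DESeq2, of which 52.1% rose against 66.3%, 5 without replicate 1, 7 without replicate 2 and 341 without replicate 3; both sites share the same 12 controls.

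In RTgill-W1, identifiers could not be paired with gene names, so counts and a few identifiers are given. The gene ENSOMYG00000004814 rose by 0.98 ± 0.041 per doubling over the 11 sites (SE; edgeR adjusted p = 9.78e-66) and was called at all 11. ENSOMYG00000029175 rose by 0.82 ± 0.0381 and was also called at 11 sites. ENSOMYG00000031234 fell by 0.32 ± 0.0304 and was called at 7 sites, 1 with libraries summed, and ENSOMYG00000018316 fell by 0.26 ± 0.0177 and was called at 6. Against DMSO, among genes with a mean of at least 10 CPM, the largest rise was that of ENSOMYG00000005060 at sites 3 and 8, by 5.90 ± 0.467 at site 3, from 1.41 ± 2.47 to 142.9 ± 21.1 CPM (SD, n = 12 and 3), and by 5.44 ± 0.472 at site 8. The largest falls were in ENSOMYG00000005236 at site 3 (-4.05 ± 0.968, adjusted p = 0.00326) and ENSOMYG00000037739 at site 8 (-3.52 ± 1.01, adjusted p = 0.0232). ENSOMYG00000004814 rose by 4.95 ± 0.606 at site 3, from 3.13 ± 3.98 to 93.5 ± 67.8 CPM, and by 4.36 ± 0.838 at site 8 (SD, n = 12 and 3).

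Over the 11 sites 373 of 1716 RTgill-W1 genes rose and 204 fell, a rising share of 64.6% that became 49.4% with upper-quartile scaling. By site, 62 rose and 42 fell at site 48, 71 and 22 at site 3, 71 and 21 at site 7, 31 and 32 at site 20, 40 and 9 at site 8, and 21 and 18 at site 30. Sites 5, 49, 2, 74 and 16 had 13, 18, 18, 10 and 4 rising and 10, 5, 3, 4 and 0 falling genes. With upper-quartile scaling the rising share moved from 85.7% to 64.3% at site 2, from 76.3% to 65.1% at site 3, from 77.2% to 63.1% at site 7, from 81.6% to 63.3% at site 8 and from 53.8% to 41.5% at site 30. Without the highest concentration the mean trend called 246 genes and site 3 called 9.

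Between sites 49 and 74, the extracts tested at matched concentrations in RTgill-W1, edgeR called 0 genes, with 89 at an unadjusted p under 0.05. DESeq2 and limma-trend also called 0, and the fit with the replicate number as a block called 1, as against 3 without the highest concentration and 9 with no filter on low counts. The highest concentration of site 3 differed from DMSO at 63 rising and 30 falling genes of 935 tested, and its lowest at 0 (47 at an unadjusted p under 0.05; other tools were not run there); the highest had 34, 19 and 76 calls without replicates 1, 2 and 3 and 37 with no filter. Site 8 had 27 rising and 25 falling genes of 737 tested at its highest concentration and 1 at its lowest, with 28, 14 and 43 calls at the highest without replicates 1, 2 and 3 and 23 with no filter.

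Finally, the number of genes called at each site was compared between the cell lines over the 11 sites. Judged on limma-trend counts, chance was not excluded at Caco-2 sites 3, 5, 7, 16, 20, 48, 49 and 74 and RTgill-W1 site 49. The edgeR counts compared here were not judged in this way. This limits what the comparison can show. On the scale of log10 of 1 plus the count, Pearson's r was 0.22 (p = 0.517) and Spearman's rho 0.214 (p = 0.524; two-sided permutation tests, n = 11), and r was 0.265 without sites 8 and 30. Over the alternatives r ran from -0.118 (p = 0.742) without the highest concentration to 0.537 (p = 0.0865) with limma-trend. The labelled concentrations differ between the lines at most sites, and no library pool held enough sites for a value within a pool. The matching comparisons of the aryl hydrocarbon receptor and metallothionein lists were not made, as trout genes could not be assigned to lists.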

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

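The tests of the wells, of the rows, of labels dealt out within runs, of the libraries with a count of 0 and of neighbouring genes were chosen after these patterns were seen; the tests of the difference between sites and the dealing out of concentrations were fixed before.

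Among the 8 Caco-2 extracts tested at matched concentrations, the slopes of 1526 genes differed (edgeR F test), for which chance could not be excluded: 429 differed in limma-trend, against 1327 in the highest other split of the wells. Of 75 named genes tested, 33 differed, and 8 of them also with the 3 libraries of a concentration summed. Metal and receptor genes that differed were MT2A (adjusted p = 4.2e-05), MT1G (0.00362), MT1X (0.00343) and TIPARP (5.74e-06; 0.0206 summed). Oxidative stress genes that differed included PRDX1 (5.41e-16; 0.00608 summed), AKR1C1 (3.45e-12; 0.0199 summed), SLC7A11 (2.27e-10; 0.00171 summed), TXN (2.51e-07), FTH1 (3.57e-06), GCLC (2.15e-05), SRXN1 (0.00141), HMOX1 (0.00684), AKR1B10 (0.0127) and TKT (0.0146). PRDX1 rose by 0.73 ± 0.0795 per doubling at site 16 and fell by 0.45 ± 0.0707 at site 74, where the fall was lost with libraries summed (adjusted p = 0.104). Heat shock and cholesterol genes that differed were HSPA1A (0.00166), HSPA1B (0.0185), HSPE1 (0.032), MSMO1 (1.96e-06), DHCR7 (0.00294) and CYP51A1 (0.0147).

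Of the genes named for rising or falling at most sites, SEL1L3 (adjusted p = 2.88e-06), SLC2A1 (1.25e-05), DNAJC15 (1.6e-07), SOX5 (0.0034), SOX6 (8.5e-05), SLC14A2 (4.89e-05), FYB2 (0.00533), NKD1 (0.000857) and CPA6 (0.0487) differed between the sites. So did FGB (2.59e-11; 0.00171 summed), PLXNC1 (1.44e-08; 0.0073 summed), FGG (6.75e-06; 0.00502 summed) and GRIK4 (1.58e-05; 0.0107 summed). No group of wells had 4 to 10 libraries, so single libraries far from their group were not sought.

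The first pattern weighed was that Caco-2 libraries of 1 site and concentration deviated from the mean of their site and run in the same way in different runs (median r over genes 0.46, 220 pairs). The trend with concentration was not taken out of these deviations. The extract and its concentration as the whole cause is excluded, since the same site and concentration in different wells gave a median of 0.0287 (30 pairs, -0.0997 to 0.274). These pairs came from sites 16 and 2, where the medians were -0.0241 (16 pairs, up to 0.0569) and 0.159 (14 pairs, up to 0.274), against 0.632 (8 pairs, from 0.519) and 0.491 (7 pairs, from 0.296) in the same well; a share of the extract at site 2 stays open. An exchange of treated and control wells within a pool is excluded too, as CYP1A1 at the highest concentration was at least 21.5 times that of the highest control in each of 6 pools. The well of the plate is the candidate explanation left open: libraries of different sites, or of a site and a control, in the same well of different runs gave a median of 0.489 (32 pairs, 0.214 to 0.714). Whether this comes from the cells, the plate or the primers placed in a well was not tested, and such deviations can enter a trend over 8 wells as if they were replicated.

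The second pattern was a count of 0 in the gene row that otherwise holds most counts, in 5 libraries, 2 of Caco-2 site 8 and 3 of RTgill-W1 sites 2 and 16, all of replicate 1. Low depth is excluded, since at least 202685 counts were due in that row from the counts elsewhere in the library. The extract is excluded as well, since the other replicates of the same sites and concentrations had at least 81.7% of their counts in that row. Gene rows set to 0 before deposit remain a candidate explanation: 1 RTgill-W1 control is held in 2 copies that differ in 386 rows, and 100% of these are 0 in the smaller copy. In the Caco-2 libraries 448 and 352 genes with at least 10 counts due were at 0, against at most 32 and 50 in the other replicates. The RTgill-W1 libraries did not show this, with 65, 33 and 65 such genes at 0 against up to 169, 122 and 132 in the other replicates. For them only the 1 gene row speaks for it. The fall of RPS28 at site 8 became a slope of 0.07 without the Caco-2 libraries. RPS28 stood there at 692 ± 1197 CPM at the lowest and 0 ± 0 CPM at the highest concentration (SD, n = 3). High counts at the lowest concentration are not rows set to 0, so RPS28 does not speak for that explanation.

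The third pattern was that genes next to the 53 most strongly rising Caco-2 genes (slope of at least 0.2) rose more often than the other located genes, of which 1290 of 12750 rose (10.1%). Of the nearest genes within 100 kb, each counted once and without those in the 53, 10 of 33 downstream rose (30.3%) and 6 of 34 upstream (17.6%). Reads shared between genes of 1 family are excluded as the whole cause, since 26.7% (8 of 30, 95% interval 12.3% to 45.9%) of the downstream genes from another family rose. A family was taken as symbols with the same first 3 letters, so MT1G past MT2A counted as another family. MT1G counted as not risen because its mean slope could not be estimated. Reads that run on past the 3' end of the rising gene cannot be told apart from joint regulation, which was not tested, since downstream and upstream shares did not differ at these numbers (Fisher's exact test, two-sided, p = 0.262). EDC3 past CYP1A1 belongs to this group, while LINC00886 and TIPARP, both among the 53, were not counted.

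As a value without explanation, genes longer than 200 kb had 155 rising and 242 falling members of 1218 in the Caco-2 mean trend, against 1343 and 1349 of 12803 located genes; with libraries summed they had 102 and 209 of 1514, against 707 and 931 of 14865.

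For each count of genes, the concentrations of a site were dealt out anew to its wells, the 3 libraries of a concentration together, or the DMSO and treated labels to the 15 libraries, and limma-trend counted the calls in 100 such splits, the real one included. Chance was judged unlikely, with 1 to 4 splits reaching the real count, in the cases that follow. The limit was fewer than 5 of 100 splits, set before, with no adjustment for the number of counts judged. In some of these cases another split exceeded the real count. Caco-2 site 2 had 456 calls and the highest other split 333 (1 split as large), site 8 had 1834 against 1907 (3 splits), site 30 had 28 against 24 (1 split), and the mean over sites had 2522 against 735 (1 split). The list and site pairs were 56 against 37 (1 split), with a median of 20 in the other splits, so single pairs may still be due to chance. Against DMSO, Caco-2 site 2 had 645 against 35 (1 split) and site 16 had 26 against 42 (2 splits). In RTgill-W1, site 2 had 34 against 28, site 3 93 against 54, site 5 9 against 5, site 8 30 against 16, site 20 25 against 8, site 30 21 against 7, site 74 9 against 5 and the mean 472 against 78, each with 1 split as large. RTgill-W1 sites 7 (161 against 167) and 48 (143 against 149) had 2 splits as large. Against DMSO, RTgill-W1 site 3 had 67 against 6 and site 8 had 58 against 9, each with 1 split.

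Treated and control libraries are paired by run, so the DMSO labels were also dealt out within runs, 1 library of each run as treated, in 100 of the 125 such splits with the run in the model. Caco-2 site 2 then had 763 calls against 115 in the highest other split (1 split as large), site 16 56 against 224 (2 splits), and RTgill-W1 sites 3 and 8 had 84 against 12 and 70 against 22 (1 split each). Without the run in the model 4 splits were as large at Caco-2 site 16 (26 against 209). A split with several times the real count, as at site 16, points to a structure of the samples. These splits leave out that wells share deviations, and 836 genes differed from DMSO at the lowest concentration of Caco-2 site 2, more than the 666 at the highest, so the count at the highest is not shown to come from the extract.

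The concentration went with the row of the plate in all 264 treated libraries of each line, so dealing out concentrations does not part the extract from a trend over rows, in single sites or in the mean. The 12 control wells lay in rows A to D. Over these rows edgeR called 0 of 8386 Caco-2 genes, with 455 at an unadjusted p under 0.05 and 0 in limma-trend, and 0 of 429 RTgill-W1 genes, with 18 and 0. Among 2084 Caco-2 genes called in the mean trend, row slopes of the controls correlated with the mean slopes at r = 0.00412, and among 154 RTgill-W1 genes at r = 0.119. The SE of a row slope, 0.131 and 0.141 at the median, exceeded the median size of the mean slopes, 0.0728 and 0.0629, and rows E to H held no control, so a row effect on single genes stays open. For CYP1A1 at sites 2 and 16 it is excluded as the whole cause, since in each of 6 pools the controls, row A included, had at most 9.98 CPM of the counts outside the row that holds most, against 214 to 1400 CPM at the highest concentration in row A.

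Chance could not be excluded for the counts of the other Caco-2 sites. The splits as large were 5 at site 3 (840 calls against 1004 in the highest other split), 18 at site 5 (496 against 827), 22 at site 7 (328 against 1089), 30 at site 16 (9 against 46) and 50 at site 20 (66 against 334). At site 48 they were 49 (117 against 858), at site 49 42 (251 against 984), at site 74 70 (44 against 621), and for the difference between the 8 sites 57 (429 against 1327). In RTgill-W1 16 splits were as large at site 49 (6 against 37). For site 16 (0 against 9) and for sites 49 and 74 (0 against 7) all 100 splits were as large because the real count was 0, which says nothing on chance. Splits with several times the real count, as at Caco-2 sites 7, 16, 20, 48, 49 and 74, point to a structure of the samples. The 3 libraries of a concentration were dealt together, so shared deviations of a well and a change by the extract at a single concentration would both give such splits, and no test parted them.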

How the results depend on the processing

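Summing libraries and leaving out the row with most counts or the libraries with a count of 0 in it were alternatives chosen after the data were seen; the cause of the changes below was not tested, except that summing and leaving out a replicate or concentration leave fewer libraries and no filter tests more genes. Counts and other main values stayed within 1.5 times, or on their side of the threshold, in 250 cases, moved further in 147 and turned sign in 1. Slopes and folds of named genes kept direction and side of the threshold in 1422 cases, became weaker in 77 and stronger in 14, and changed sign in 21. Depth limits RTgill-W1 most, where 1716 genes had enough counts to test, and the lists and list correlations planned for that line were not run.

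With the libraries summed, Caco-2 sites 2, 3, 5, 7, 8, 16, 20, 30, 48, 49 and 74 had 264, 431, 172, 141, 626, 35, 9, 16, 50, 91 and 32 calls, the mean trend 1665 and the difference between 8 sites 92; RTgill-W1 sites 3, 5, 16, 20, 30, 48 and 49 had 51, 14, 1, 33, 18, 66 and 14.

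Without the highest concentration, Caco-2 sites 2, 3, 7, 8 and 49 had 437, 707, 294, 868 and 258 calls, the mean trend 1707 and the list and site pairs 35. RTgill-W1 sites 2, 3, 7, 8, 16, 20, 30, 48, 49 and 74 had 12, 9, 31, 8, 0, 14, 20, 56, 10 and 9, the mean trend 246 and sites 49 against 74 3. The correlation between the lines turned to r = -0.118, while it was 0.537 with limma-trend and 0.435 with no filter.

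With limma-trend, Caco-2 sites 5, 16, 20, 30, 48, 49 and 74 had 496, 9, 66, 28, 117, 251 and 44 calls, the 8 sites 429 and site 16 against DMSO 26; RTgill-W1 sites 2, 5, 7, 8, 16, 20, 30, 49 and 74 had 34, 9, 161, 30, 0, 25, 21, 6 and 9. With no filter, Caco-2 sites 20 and 30 had 476 and 244 and site 16 against DMSO 268. RTgill-W1 sites 2, 5, 8, 16, 20, 49 and 74 then had 46, 54, 79, 31, 103, 89 and 35, the mean trend 949, sites 49 against 74 9, and sites 3 and 8 against DMSO 37 and 23. DESeq2 gave 47, 1 and 173 at RTgill-W1 sites 2, 16 and 48 and 215 at Caco-2 site 16 against DMSO; upper-quartile scaling gave 1 at RTgill-W1 site 16. An estimated correlation left 34 list and site pairs.

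The replicate number as a block gave 180 calls for Caco-2 site 16 against DMSO and 1 for RTgill-W1 sites 49 against 74, and moved no other count by over 1.5 times. It also ended the call of the interferon list at sites 7 and 20 (adjusted p = 0.066 and 0.0742). The block brought in the fatty acid oxidation list at site 3 (0.0373) and the heat shock list at site 16 (0.048). With an estimated correlation and no block these 2 had 0.304 and 0.516, and with libraries summed 0.0255 and 0.183. The block moved GPX2 to an adjusted p of 0.0558 and MVD to 0.0365 in the mean trend, and changed no other call of a list or named gene.

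Leaving out each replicate in turn gave these ranges of calls in Caco-2: 271 to 444 at site 2, 546 to 817 at site 3, 384 to 437 at site 5, 176 to 319 at site 7, 770 to 966 at site 8, 64 to 190 at site 16, 53 to 62 at site 20, 47 to 85 at site 30, 134 to 168 at site 48, 176 to 264 at site 49 and 121 to 138 at site 74. The mean trend had 1578 to 2228, the 8 sites 578 to 712, and sites 2 and 16 against DMSO 220 to 592 and 5 to 341. In RTgill-W1 the ranges were 13 to 27 at site 2, 37 to 55 at site 3, 12 to 20 at site 5, 31 to 88 at site 7, 19 to 44 at site 8, 0 to 3 at site 16, 21 to 42 at site 20, 16 to 41 at site 30, 38 to 68 at site 48, 10 to 17 at site 49 and 6 to 8 at site 74. The mean trend had 337 to 600 there, and sites 3 and 8 against DMSO 19 to 76 and 14 to 43.

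The slopes that changed sign were in genes below the threshold, apart from AK4P3 at site 2 (-0.94 to 0.00024 over the replicates left out) and RPS28 at site 8 (-2.07 to 0.018; 0.067 without the libraries with a count of 0). Over the replicates left out ABCC2 ranged from -0.0045 to 0.013, TKT from -0.013 to 0.012, FTH1 from -0.016 to 0.011, MSMO1 from -0.021 to 0.011, FDFT1 from -0.018 to 0.0031 and LSS from -0.024 to 0.032. Without the highest concentration ABCC2, TKT, IDI1 and FDPS were at -0.00428, 0.0131, 0.00299 and 0.00302. With limma-trend TKT, FTH1, MSMO1 and FDFT1 were at 0.0165, 0.0234, 0.0103 and 0.00111. Without the libraries with a count of 0 TKT, FTH1 and FDFT1 were at 0.0036, 0.0044 and 0.0046, and FTH1 was at 0.0084 with the libraries summed.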

Other observations

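Several gene lists moved in part without a call at most sites. In the xenobiotic metabolism (PXR) list 2 of 8 Caco-2 members rose in the mean trend and 5 fell, 8 over the list alone, with no call of the list at any site. The efflux pump ABCG2 rose by 0.22 ± 0.0268 per doubling and UGT1A1, which shares exons with its UGT1A neighbours, by 0.18 ± 0.0407, while the glucuronosyltransferase UGT2B7 fell by 0.17 ± 0.0214, the pump ABCB1 fell by 0.12 ± 0.0256, GSTA1 fell by 0.11 ± 0.0311 and CYP3A5 fell by 0.08 ± 0.0249. Of 6 interferon genes 4 fell, 4 also over the list alone. That list was called down at sites 7 and 20 (adjusted p = 0.0389 and 0.0391), both lost with an estimated correlation (adjusted p = 0.172 and 0.172) and with the replicate number as a block (0.066 and 0.0742). Immediate early genes were called up at sites 7, 8 and 16 (adjusted p = 0.00498, 0.0441 and 0.00377; at site 8 0.1 with an estimated correlation), and 3 of 8 rose in the mean trend, 4 over the list alone, with MYC at 0.17 ± 0.0222. In the p53 list 4 of 11 rose and 1 fell, 5 over the list alone, with no call at any site; GDF15, a stress cytokine, had a slope of 0.15 ± 0.0246. The NF-kB list had 1 of 5 rising, 1 over the list alone, and no call at any site.

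Cholesterol synthesis was called up at site 7 and down at site 20 (adjusted p = 0.0215 and 0.0328), both lost with an estimated correlation (adjusted p = 0.347 and 0.379). In the mean trend 2 of its 17 members rose, INSIG1 (0.11 ± 0.0254) among them, and 1 fell, with 4 past over the list alone. Hypoxia and glycolysis was called up at site 30 (adjusted p = 0.00186; 0.114 with an estimated correlation), with 4 of 13 rising and 1 falling, 6 over the list alone; SLC2A1 rose and ADM, adrenomedullin, fell by 0.13 ± 0.0243. In the fatty acid oxidation list 4 of 9 rose and 1 fell, 6 over the list alone, with PLIN2, a lipid droplet coat protein, at 0.16 ± 0.0194. In the unfolded protein response list 1 of 14 rose and 1 fell, 2 over the list alone, and in the proliferation list 2 of 16 fell, 2 over the list alone. Of 20 ribosomal proteins 7 rose and 1 fell, 11 over the list alone, and 2 rose and 0 fell with libraries summed; the calls at sites 2, 3 and 48 (adjusted p = 0.0018, 0.0112 and 0.0196) had adjusted p of 0.394, 0.532 and 0.58 with an estimated correlation. At site 8 the ribosomal list went down without a call (adjusted p = 0.0706), with 7 members falling and 0 rising, 3 falling with libraries summed. The 2 lowest concentrations of site 8 each include a library with a count of 0 in the row that holds most counts. Without these libraries the fall of the ribosomal gene RPS28 there became a slope of 0.07. The falls of the list without them are not given here. At the called sites 2, 1 and 2 members rose, and 1 fell at site 48. Mitochondrially encoded genes were called up at site 74 and down at site 7 (adjusted p = 2.09e-05 and 0.0361; 0.241 and 0.608 with an estimated correlation), and 1 of 13 rose in the mean trend, 1 over the list alone.

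Of 10 enterocyte genes 3 rose and 2 fell, 6 over the list alone, with no call at any site; the keratin KRT20 had a slope of 0.19 ± 0.0491 and the brush border protein VIL1 of -0.09 ± 0.0136. Of 3 genes of other intestinal lineages LGR5, a stem cell marker, fell by 0.10 ± 0.0184, 1 over the list alone, with no call of the list. Epithelial markers were called down at site 20 (adjusted p = 0.0128; 0.203 with an estimated correlation), and 1 of 9 rose and 1 fell in the mean trend, 2 over the list alone, the latter being the cadherin CDH1 (-0.06 ± 0.0106). At sites where a list was called, no member passed over all genes for cholesterol synthesis at site 7, mitochondrially encoded genes at site 7, and interferon genes and epithelial markers at site 20. With libraries summed the calls of the interferon list at site 7 (adjusted p = 0.0727) and of the cholesterol list at site 20 (0.0643) were lost. In the mean trend with libraries summed, 2 interferon genes and 1 enterocyte gene fell, no p53 gene fell and no epithelial marker rose. In that mean trend no member rose or fell in the unfolded protein response, proliferation, NF-kB and mitochondrially encoded lists. Of 4 mesenchymal, immune and blood markers 1 rose, FN1 for fibronectin (0.04 ± 0.0103), 1 over the list alone, with no call at any site.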
